A study of Mus musculus with 2 samples.

How the data were processed

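H3K27me3 ChIP-seq was done on forebrain of mouse embryos at embryonic day 16.5, in 2 biological replicates, each a pool of male and female embryos, per the labels. Fragments ran from 300 to 500 bp, per the labels. The labels name a possible control experiment; whether and how it was used is not given in the sources used here. The aligner, the peak caller, their versions and the thresholds are likewise not given in the sources used here. Coordinates are those of mm10 (GRCm38), per the deposited text lists that accompany the peaks.

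The deposited data are 4 peak lists in narrowPeak format. According to the deposited text lists, the authors called peaks in replicate 1 alone, in replicate 2 alone and in both together (the pooled set), and kept a subset of the pooled peaks as replicated. The rule for that subset is not stated. All 25094 replicated peaks are also in the pooled list of 34655. The same text lists give replicate 1 and the pooled set as derived from the alignments and 2 further files, and replicate 2 from its alignments and 1 of those files, with no roles stated. In the deposited lists each peak has a signal, an enrichment measure whose reference is not stated. Each also has a −log10 p-value and a −log10 q-value, as the authors' peak caller gave them in the deposited lists. The lowest −log10 p in the replicated list is 2.05, so the lists hold weak peaks. Signal, p and q were used to rank or filter peaks within a list, with p as the rank for equal peak numbers. In the closing section signal was also used to compare the highest signal at groups of genes within the replicated list. Because peak number and height depend on depth and on the caller, a replicate with fewer peaks does not show less of the mark, and broad enrichment between narrow peaks is not recorded.

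Gene models came from GENCODE mouse release 21 (GRCm38), with 21938 protein-coding genes and 93513 transcription start sites on the autosomes, X and Y. The RefSeq GRCm38 sequence served for chromosome lengths, assembly gaps and CpG ratios. No peak ran past a chromosome end and no peaks of a list overlapped each other. A gene was counted as marked when a peak overlapped by 1 bp or more the 1 kb on either side of any of its start sites. CpG classes used the observed over expected CpG ratio in the 500 bp on each side of the 5′ end, with bounds at 0.35 and 0.6. Domains joined peaks over gaps of up to 3 kb. Random expectations came from 100 placements of the peaks on their own chromosomes outside assembly gaps of 1000 bp or more, with fixed seeds.

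Gene lists (24), gene families by symbol (26) and 3 comparisons of lists were fixed before the data were examined, and 543 of 544 list symbols were found among protein-coding genes. Each list or family was compared with all other protein-coding genes, and each pair of lists after genes in both were left out, by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment within lists, families and pairs. These p-values describe genes of 1 tissue, not variation between embryos. Values per replicate are given as mean ± SD with n = 2. Intervals of shares are 95% Wilson intervals and cover counting error only. Named genes followed a rule set beforehand: genes with a start site in the 15 longest domains (up to 6 per domain), the 25 genes with the most replicated-peak bases in the 10 kb around a start site (at most 2 per domain), and of each list up to 4 members with the most such bases, up to 4 without a promoter peak in either replicate and up to 2 with a promoter peak in only 1. Where a gene has several start sites, the window with the most bases was used, whereas the promoter call used all of them. Members of gene families are named by their symbol stem.

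Interval code was checked against bedtools 2.31.1, which gave the same number of overlapped replicate 1 peaks (difference 0 over 58084). It was also tested on simulated data: peaks implanted at 200 promoters were recovered in 100%, an implanted list share of 81.0% was measured as 81.0%, a built overlap of 50.2% was measured as 50.5%, and random lists of 20 and 40 genes passed an unadjusted p of 0.05 in 3.70% and 3.50% of 1000 draws. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, pysam 0.24.0 and matplotlib 3.10.9.

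The alternatives compared were the pooled set, each replicate alone, peaks of −log10 q of 5 or more, peaks of signal at or above the median, windows of 500 bp and 2.5 kb, the 5′ end only, an overlap of 200 bp or more, CpG-rich promoters only, clustered genes counted once, autosomal genes only, joins over 1 kb and 10 kb, equal peak numbers and an overlap of 50% of the peak. Chosen after seeing the data were replicated peaks touched by both replicates, and autosomes only for the replicate comparison. Reads, alignments and control libraries were not analysed here.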

Results

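Trimethylation of lysine 27 on histone H3 (H3K27me3), the mark that Polycomb repressive complex 2 writes over repressed genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the mouse forebrain at embryonic day 16.5. The forebrain gives rise to the cortex, the hippocampus, the basal ganglia and the diencephalon, and at this age it holds progenitors and young neurons together. The series has 1 group with 2 biological replicates, each a pool of B6NCrl embryos of both sexes. Replicate 2 came from 41 embryos, and the number behind replicate 1 is not stated in the labels. Replicate 1 gave 58084 peaks that covered 21.3 Mb of the genome, and replicate 2 gave 30831 peaks that covered 10.8 Mb. A peak set of both replicates together held 34655 peaks. Its subset called replicated held 25094 peaks over 15.01 Mb, or 0.551% of the genome, and is the main set below. The peak lists carry no read counts, so sequencing depth is unknown. There is no second tissue, age or genotype, so the comparisons are between the replicates, between sets of genes and between parts of the genome.

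H3K27me3 peaks of high signal were shared by the replicates more often than peaks of low signal. Of the replicate 1 peaks, 17248 (29.7%) were overlapped by a replicate 2 peak by at least 1 bp, against a mean of 0.923% when replicate 2 was placed at random within chromosomes. Of the replicate 2 peaks, 19531 (63.3%) were overlapped by replicate 1, against 1.73% at random. In the highest signal quartile of each list these shares were 62.8% for replicate 1 and 92.2% for replicate 2, and in the lowest quartile they were 14.1% and 40.5%. With peaks of −log10 q of 5 or more, 8038 and 1129 peaks were left, of which 13.2% and 90.4% were overlapped. Covered bases had a Jaccard index of 27.1%, against 0.307% at random. The lists reach far down: 76.6% of replicate 1 peaks and 36.4% of replicate 2 peaks had a q-value of 0.05 or less, as did 82.6% of the replicated peaks. Of the 25094 replicated peaks, 14548 were touched by peaks of both replicates, 8196 by replicate 1 alone, 1523 by replicate 2 alone and 827 by neither.

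**Figure D1:**
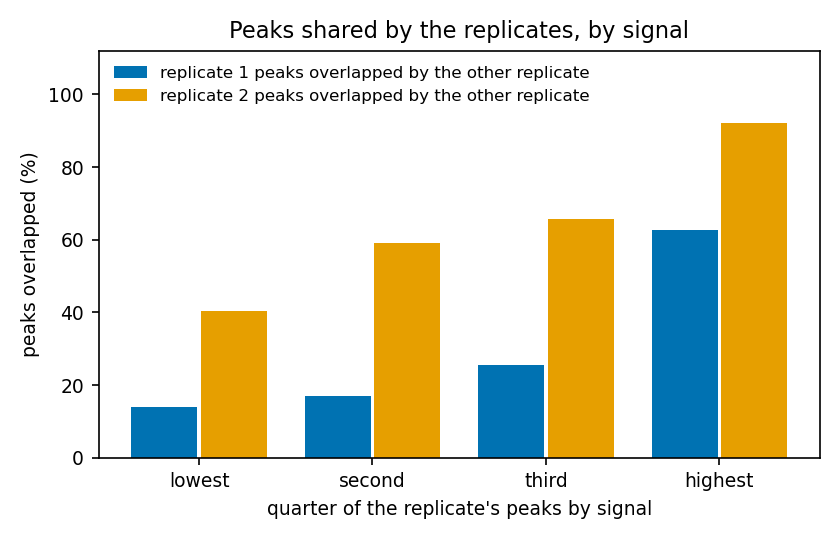
Share of peaks of each replicate (y axis, percent) that a peak of the other replicate overlaps by at least 1 bp, for each signal quartile of that replicate's peaks, by the deposited signal (x axis). The share rises from 14.1% to 62.8% for replicate 1 and from 40.5% to 92.2% for replicate 2.

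H3K27me3 was concentrated at promoters. Promoters, taken as 1 kb on each side of any transcription start site (TSS) of a protein-coding gene, held 21.5% of the bases under replicated peaks, 5.12-fold the mean of 100 random placements. Exons held 8.59% (2.10-fold), introns 35.8% (0.865-fold) and intergenic sequence 34.1% (0.677-fold). In the individual replicates the promoter share was 17.0% and 19.3%. Of 21938 protein-coding genes, 2819 had a replicated peak at a promoter (12.8%, 95% Wilson interval 12.4% to 13.3%, which covers counting error only), and no random placement gave more than 1381. Replicate 1 marked 3890 genes and replicate 2 marked 2675, a mean of 14.96% ± 3.92 (SD, n = 2). Both replicates marked 2374 genes, 1516 were marked in replicate 1 alone and 301 in replicate 2 alone, with a Cohen's kappa of 0.676 (0.272 with peaks of −log10 q of 5 or more, which left 243 genes in both). Of the 2819 genes with a replicated peak, 2265 were marked in the lists of both replicates and 554 were not. With only peaks of −log10 q of 5 or more, 5.04% of genes were marked.

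The 4 Hox clusters, which encode the transcription factors of the body axis behind the forebrain, carried long stretches of the mark. All 39 Hox cluster genes had a promoter peak in the replicated set and in each replicate, against 12.7% of other genes (Fisher's exact test, two-sided, adjusted p = 1.68e-34). Neighbouring Hox genes share domains and are not independent. Over the alternatives the adjusted p of Fisher's exact test ran from 2.41e-47 to 4.81e-04. Peaks covered 82.8% ± 9.21 (SD, n = 2) of HoxC on chromosome 15, 80.6% ± 8.75 of HoxA on chromosome 6, 76.3% ± 12.0 of HoxD on chromosome 2 and 68.8% ± 10.3 of HoxB on chromosome 11. Flanks of the same length, averaged over both sides, were covered to 26.2% ± 9.43, 24.3% ± 4.13, 11.2% ± 2.13 and 12.2% ± 2.94 in the same order, below the cluster in both replicates in each case. The sides were unequal. In the replicated set the left and right flanks were covered to 14.5% and 47.8% for HoxC and 7.72% and 45.6% for HoxA. For HoxD they were covered to 19.9% and 3.70%, and for HoxB to 19.2% and 6.32%. Replicate 2 covered less of each cluster than replicate 1, for HoxD 67.8% against 84.8%. The HoxD cluster lies at chromosome 2 from 74668310 to 74765142 (mm10), and the marked region continued past Hoxd13 over Evx2, a homeobox gene beside the cluster.

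**Figure D2:**
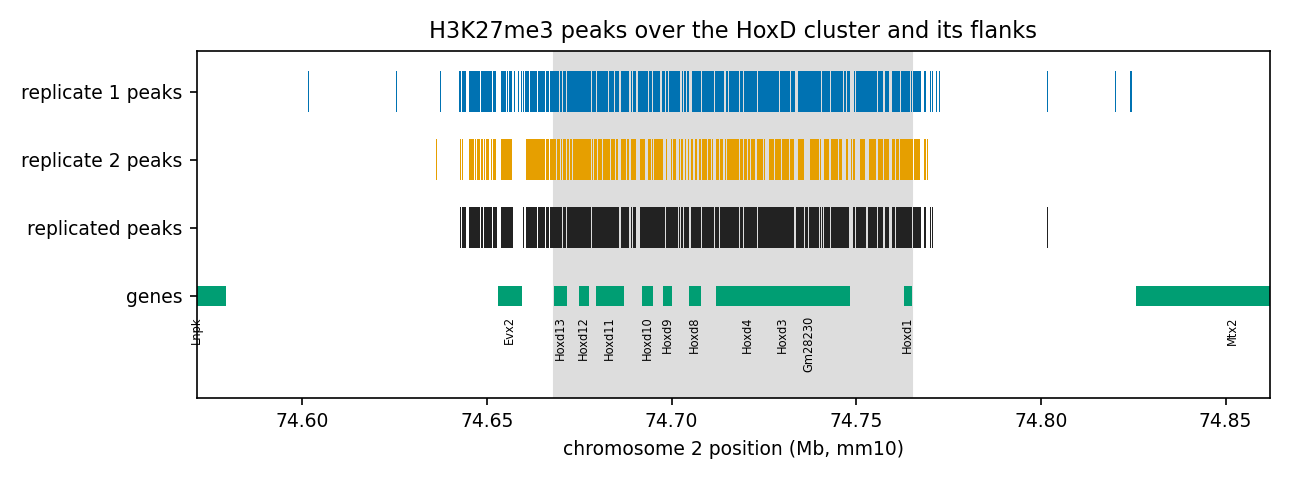
Map of chromosome 2 (x axis, Mb, mm10) over the HoxD cluster (grey, 74668310 to 74765142) and a flank of the same length on each side, with the peaks of replicate 1, replicate 2 and the replicated set as filled bars and protein-coding genes in green. Replicated peaks cover 87.6% of the cluster, 19.9% of the left flank and 3.70% of the right flank.

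When replicated peaks up to 3 kb apart were joined, they formed 7805 domains with a median length of 924 bp, of which 1368 were longer than 5 kb and 534 longer than 10 kb. The 4 longest lay over Hox clusters. They spanned 196.2 kb at chromosome 15 from 102895526 to 103091763 (HoxC), 182.0 kb at chromosome 6 from 52144976 to 52326947 (HoxA), 147.7 kb at chromosome 11 from 96233309 to 96380975 (HoxB) and 128.2 kb at chromosome 2 from 74642599 to 74770786 (HoxD with Evx2). Next came 107.6 kb at chromosome 12 from 56441408 to 56549021 around Nkx2-1, a factor of the ventral forebrain, lung and thyroid, and 90.7 kb at chromosome 1 from 78131393 to 78222107 around Pax3, a factor of the neural crest and dorsal spinal cord. Ebf3 (66.6 kb), Dmbx1 (60.6 kb), Nr2f2 (60.6 kb), Hoxb13 (58.2 kb), Tbx5 (57.8 kb), Zic4 (54.4 kb) and the pair Cdkn2a and Cdkn2b (49.7 kb), cell cycle inhibitors of the senescence pathway, lay in further domains of the 15 longest. The other 2 of the 15 held no TSS of a protein-coding gene. The number and length of domains depended on the peak list. Replicate 1 alone gave 22482 with a median of 250 bp, of which 2386 were over 5 kb and 900 over 10 kb. Replicate 2 alone gave 11630 with a median of 266 bp, of which 1204 were over 5 kb and 485 over 10 kb.

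Ranked by replicated-peak bases in the 10 kb around the TSS, with at most 2 genes per domain, the first 25 protein-coding genes carried 9074 to 9923 bp of peaks, and all 25 had a promoter peak in both replicates. Hox genes made up 9 of them: Hoxc12, Hoxd11, Hoxa3, Hoxc6, Hoxb3, Hoxb13, Hoxd12, Hoxb9 and Hoxa7. Hoxc12 (chromosome 15, 102936757 to 102938609) led with 9923 bp, and the replicates covered 8950 ± 775 bp (SD, n = 2) of its window. T-box factors made up 4: T (8064 ± 1559 bp), which specifies the primitive streak and notochord, Tbx1 (7575 ± 2193 bp), Tbx3 (8358 ± 1006 bp) and Tbx15 (7197 ± 1766 bp). Factors of other regions or tissues followed, among them Cdx2 (8850 ± 776 bp) of the gut, Mnx1 (8499.5 ± 79.9 bp) of motor neurons, Nkx2-2 (8131 ± 1061 bp) of the ventral neural tube, Foxf1 (8043 ± 1441 bp) of visceral mesoderm and Hmx1 (8840 ± 1131 bp), Nkx1-1 (7245 ± 1705 bp) and Msx2 (7836 ± 1308 bp), which are homeobox factors. The secreted ligand Wnt10b (8835 ± 326 bp) and the retinoic acid degrading enzyme Cyp26a1 (7421 ± 1306 bp) were on the list, as were the hormone gene Insl3 (8875 ± 1289 bp), the heat shock factor gene Hsf4 (8243 ± 996 bp) and the cytokine-induced gene Tnfaip2 (7384 ± 2729 bp). In all 25 windows replicate 1 covered more bases than replicate 2, from 8344 to 9848 bp against 5454 to 8711 bp.

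Within the nervous system, factors of regions behind the forebrain carried the mark more often than factors of the forebrain itself. All 42 factors of the midbrain, hindbrain and spinal cord had a promoter peak, among them Lhx3 (7158.5 ± 1346 bp) of motor neurons and Ptf1a (7296.5 ± 1859 bp) of inhibitory neurons. Of the 63 forebrain factors in 3 lists, 37 (58.7%) had one (Fisher's exact test, two-sided, adjusted p = 6.82e-07 over 3 list pairs). The lists are preset groupings, and a member may also act in other regions. The ventral list includes Gad1, Gad2, Sst and Npy, which do not encode transcription factors. In the replicates the forebrain share was 62.7% ± 7.86 and the other share 98.8% ± 1.68 (SD, n = 2). Base counts in parentheses after gene names are the peak bases in the 10 kb around the TSS, as mean ± SD of both replicates (n = 2). Telencephalic patterning factors were marked in 12 of 20 (60.0%, adjusted p = 2.20e-06 against other genes by Fisher's exact test): Six3 (7235 ± 994 bp), Pax6 (3779.5 ± 2980 bp), Nr2f2 (4925.5 ± 746 bp) and Dmrta2 (3947.5 ± 1231 bp) were marked in both replicates. Foxg1, the factor that defines the telencephalon, Tcf4, Hes5 and Sox2 had no promoter peak in either replicate, and Emx2 and Otx1 had one in replicate 1 and the replicated set but not in replicate 2.

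Ventral factors were marked more often than cortical ones. Ventral telencephalon and interneuron factors were marked in 17 of 22 (77.3%) and cortical excitatory neuron factors in 8 of 21 (38.1%), which differed by Fisher's exact test, two-sided (adjusted p = 0.0139). The replicates gave 81.8% ± 6.43 and 40.5% ± 3.37 (SD, n = 2). Lhx6 (6568.5 ± 3197 bp) of migrating interneurons, Gsx1 (7416.5 ± 1552 bp) and Gsx2 (6035.5 ± 1487 bp) of ventral progenitors and Ebf1 (5794.5 ± 1422 bp) had the most replicated-peak bases among ventral factors, while Ascl1 and Meis2 had no promoter peak in either replicate. Of the replicates, Dlx2 had one in replicate 1 only and Arx in replicate 2 only. Among cortical factors Neurog1 (6329.5 ± 2238 bp), Satb2 (4002.5 ± 1965 bp) of upper-layer neurons, Fezf2 (3365.5 ± 2009 bp) of deep-layer neurons and Eomes (2985.5 ± 1556 bp) of intermediate progenitors were marked, and Bcl11b, Neurod6, Neurog2 and Mef2c had no promoter peak in either replicate. The mark around Neurog2 lay away from its TSS, with 1941.5 ± 1645 bp in the 10 kb window. The cortical list differed from other genes (adjusted p = 0.00475 by Fisher's exact test). That call was lost among CpG-rich promoters alone, where 4 of 13 were marked (adjusted p = 0.147), with peaks of −log10 q of 5 or more, where 2 of 21 were (adjusted p = 0.404, Fisher's exact test), or with peaks of signal at or above the median, where 5 of 21 were (adjusted p = 0.0536, Fisher's exact test). Over its alternatives the adjusted p of Fisher's exact test ran from 0.00166 to 0.404. The call between cortical and ventral factors was lost, with the direction kept, with peaks of −log10 q of 5 or more (9.52% against 36.4%, adjusted p = 0.0689) and with the 5′ end of each gene as its only TSS (38.1% against 68.2%, adjusted p = 0.0690, the highest in a range from 0.00159, Fisher's exact test).

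**Figure D3:**
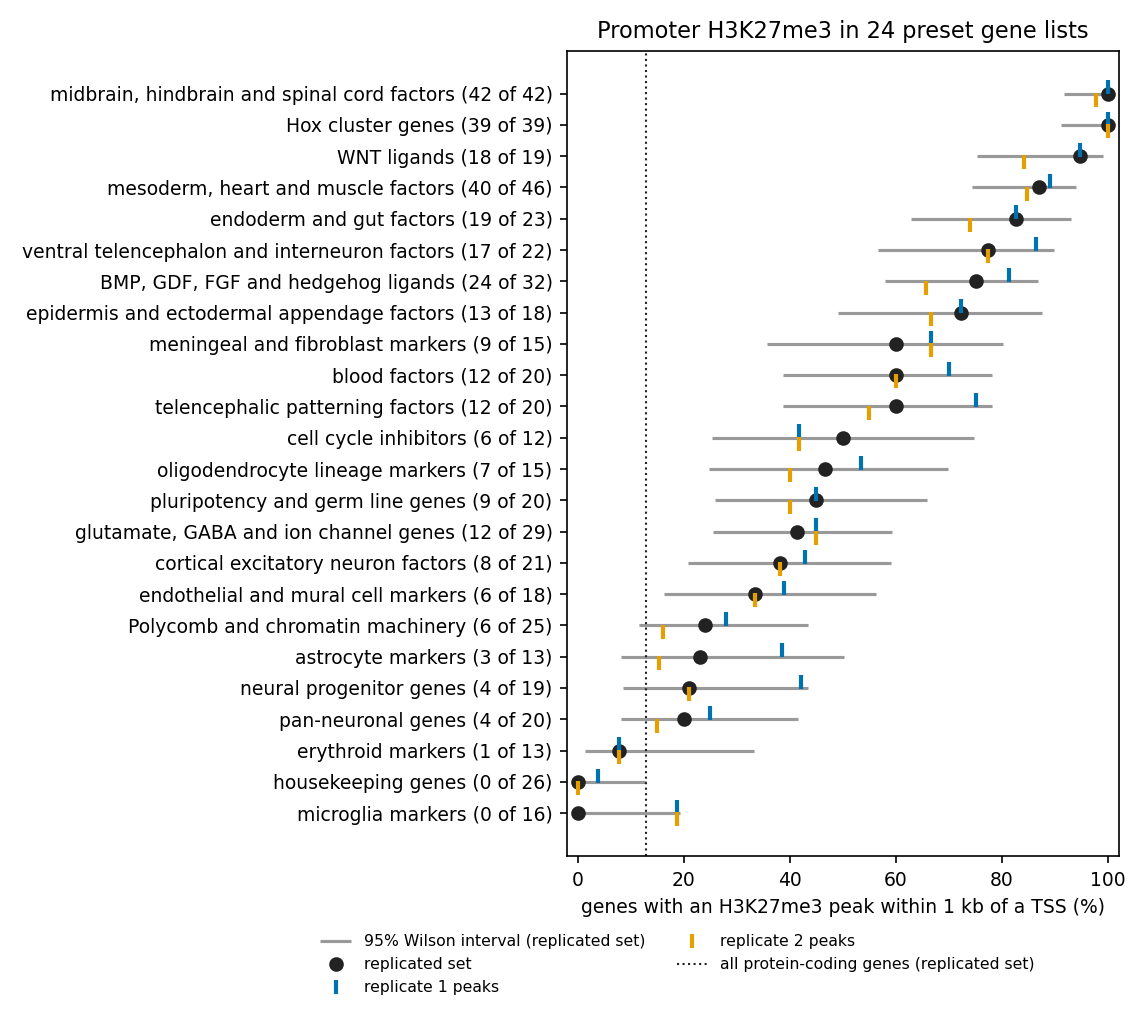
Share of genes with an H3K27me3 peak within 1 kb of a TSS (x axis, percent) for the 24 gene lists (y axis, with marked genes of list members), in the replicated set (black, with 95% Wilson intervals in grey), in replicate 1 (blue) and in replicate 2 (orange). The dotted line is the 12.8% of all protein-coding genes, and the shares run from 0 of 16 microglia markers to 42 of 42 midbrain, hindbrain and spinal cord factors.

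Factors of mesoderm, endoderm, blood and epidermis also carried the mark in most cases. The epidermis list includes keratin genes, Cdh1 and Epcam, which do not encode transcription factors. Of 46 mesoderm, heart and muscle factors 40 were marked (87.0%, adjusted p = 6.04e-29), of 23 endoderm and gut factors 19 (82.6%, adjusted p = 2.35e-13), of 20 blood factors 12 (60.0%, adjusted p = 2.20e-06) and of 18 epidermis and ectodermal appendage factors 13 (72.2%, adjusted p = 3.47e-08), all by Fisher's exact test against other genes. Together the mesoderm, endoderm and blood factors were marked in 70 of 87 (80.5%), more often than 36 of 61 forebrain factors not shared with them (59.0%, adjusted p = 0.00831 by Fisher's exact test). With a window of 2.5 kb that comparison missed the threshold (70.5% against 82.8%, adjusted p = 0.108, Fisher's exact test, the highest in a range from 8.05e-08 over the alternatives). Foxa1 (7331 ± 1772 bp), a pioneer factor of endoderm, Pdx1 (7568 ± 1749 bp) of the pancreas, Pax5 (6086.5 ± 2234 bp) of B cells, Runx1 (5944.5 ± 1054 bp) of blood stem cells and Tfap2a (7472.5 ± 1377 bp) of skin and neural crest were marked in both replicates. Exceptions with no promoter peak in either replicate were the muscle factors Myf5, Myf6 and Myog and the mesoderm factor Msgn1, the liver and gut factors Hnf1a, Hnf4a, Hnf4g and Isx, the blood factors Gata1, Spi1 and Klf1, and Trp63, Krt5, Krt14 and Foxn1 of the epidermis.

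Secreted signals were marked at most of their genes. Of 19 WNT ligands 18 had a promoter peak (94.7%), with Wnt10b (8834.5 ± 326 bp), Wnt10a (5561.5 ± 2864 bp), Wnt1 (7509 ± 134 bp) and Wnt3a (6044.5 ± 1708 bp) ahead by replicated-peak bases and Wnt7a the exception. Of 32 BMP, GDF, FGF and hedgehog ligands 24 did (75.0%), with Bmp4 (5843.5 ± 2312 bp), Ihh (6656 ± 1001 bp), Fgf8 (6693 ± 652 bp) and Shh (6992 ± 1056 bp) ahead, and Gdf1, Gdf3, Gdf5 and Gdf11 without a promoter peak in either replicate. Both lists had an adjusted p of 6.97e-15 by Fisher's exact test. Cell cycle inhibitors were marked in 6 of 12 (adjusted p = 0.00331, Fisher's exact test), with Cdkn2a (7504 ± 754 bp), Cdkn2b (5506.5 ± 1925 bp), Trp73 (4066.5 ± 257 bp) and Cdkn1c (2837.5 ± 754 bp) ahead and Cdkn1b, Cdkn2d, Rb1 and Rbl1 without a peak in either replicate. Each replicate alone marked 5 of the 12, and without replicate 2 the list missed the threshold (adjusted p = 0.0615, Fisher's exact test), as it did with the 5′ end as the only TSS (adjusted p = 0.173, the highest in a range from 0.00223, Fisher's exact test). Pluripotency and germ line genes were marked in 9 of 20 (45.0%, adjusted p = 7.68e-04, Fisher's exact test): Utf1 (4073.5 ± 2529 bp), Prdm1 (3937 ± 605 bp), Esrrb (3951 ± 1875 bp) and Prdm14 (3324 ± 1039 bp) carried the mark, and Nanog, Zfp42, Dppa2 and Dppa3 had no promoter peak in either replicate.

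Of the genes that neurons use broadly, 4 of 20 were marked (20.0%, Wilson interval 8.07% to 41.6%, adjusted p = 0.328), and of neural progenitor genes 4 of 19 (21.1%, 8.51% to 43.3%, adjusted p = 0.321), neither past the threshold by Fisher's exact test. Tubb3, Map2, Dcx and Snap25 had no promoter peak in either replicate, nor had Vim and Fabp7 of radial glia. The marked members included Rbfox3 (3796.5 ± 1125 bp), a marker of mature neurons, Nefl (2972 ± 1802 bp), Crmp1 (1967 ± 1055 bp), Pax6 and Hopx (1702 ± 1424 bp). Replicate 1 alone marked 8 of 19 progenitor genes, past the threshold (adjusted p = 0.0172, the lowest in a range up to 1.00, Fisher's exact test), and replicate 2 alone 4 of 19. Glutamate, GABA and ion channel genes were marked in 12 of 29 (41.4%, adjusted p = 2.47e-04, Fisher's exact test). Slc32a1 (3531 ± 1424 bp) and Slc17a7 (5017.5 ± 2331 bp), the vesicular transporters of GABA and of cortical glutamate, and the NMDA receptor genes Grin2a (3392 ± 2212 bp) and Grin1 (2853.5 ± 1074 bp) were marked, and the AMPA receptor genes Gria1, Gria2, Gria3 and Gria4 were not marked in either replicate. With peaks of −log10 q of 5 or more this list missed the threshold (adjusted p = 0.0889, the highest in a range from 1.87e-05, Fisher's exact test).

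Of the other cell types that a forebrain dissection can hold, markers of oligodendrocytes, meninges and blood vessels were marked more often than other genes. Oligodendrocyte lineage markers were marked in 7 of 15 (46.7%, adjusted p = 0.00246), meningeal and fibroblast markers in 9 of 15 (60.0%, adjusted p = 4.96e-05) and endothelial and mural markers in 6 of 18 (33.3%, adjusted p = 0.0297), by Fisher's exact test. Some marked members were also counted in lists above. These are Nkx2-2 (midbrain, hindbrain and spinal cord), Foxc1, Tbx18 and Twist1 (mesoderm), Bmp7 (ligands) and Sox17 (endoderm). The marked members with the most replicated-peak bases were, list by list, Nkx2-2, Olig1 (7533.5 ± 1496 bp), Olig2 (5245.5 ± 1169 bp) and Pdgfra (4552.5 ± 1809 bp), then Foxd1 (6493 ± 126 bp), Bmp7 (5196.5 ± 1865 bp), Twist1 (4613.5 ± 1401 bp) and Aldh1a2 (5288 ± 646 bp), then Sox17 (4747 ± 812 bp), Flt1 (4534 ± 1662 bp), Sox18 (5120.5 ± 548 bp) and Kdr (4026.5 ± 829 bp). The myelin genes Mbp, Plp1, Mog and Mag, the fibroblast matrix genes Col3a1, Dcn and Lum, and Pecam1, Cdh5, Tek and Tie1 of endothelium had no promoter peak in either replicate. Astrocyte markers (3 of 13, 23.1%, adjusted p = 0.274), microglia markers (0 of 16, adjusted p = 0.287) and erythroid markers (1 of 13, Epor, adjusted p = 1.00) did not pass the threshold by Fisher's exact test. Replicate 1 alone marked 5 of 13 astrocyte markers (38.5%) and replicate 2 alone 2 of 13 (15.4%). Lists of 13 and 16 genes could not pass it on the lower side in the replicated set, since none marked gives an unadjusted p of 0.396 and 0.251 by Fisher's exact test. Each replicate alone marked 3 of 16 microglia markers, with C1qc in both but not in the replicated set. The endothelial call ended with a window of 2.5 kb (adjusted p = 0.0760) and with peaks of −log10 q of 5 or more (adjusted p = 0.0889, the highest in a range from 0.00354, both Fisher's exact test).

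Of 26 housekeeping genes none had a replicated promoter peak (Wilson interval 0% to 12.9%), and Reep5 alone had one in a single replicate. This did not pass the threshold (adjusted p = 0.0924, Fisher's exact test), though it did with the pooled set (0 of 26, adjusted p = 0.0338, the lowest in a range up to 0.768, Fisher's exact test). Polycomb and chromatin machinery genes were marked in 6 of 25 (24%, adjusted p = 0.157, Fisher's exact test), with 7 of 25 in replicate 1 and 4 of 25 in replicate 2. The core genes of Polycomb repressive complex 2, Ezh1, Ezh2, Eed and Suz12, had no promoter peak in either replicate. Cbx8 (4202 ± 1270 bp) and Phf19 (1552.5 ± 654 bp), which encode Polycomb subunits, were marked in both, and Pcgf1 (3517 ± 636 bp) and Cbx4 (1933.5 ± 1247 bp) in replicate 1 and in the replicated set. In all, 17 of the 24 lists were marked more often than other genes past an adjusted p of 0.05, none less often, and 7 did not pass. For 19 of the 24 lists, those of up to 26 genes, a lower share could not pass in the replicated set, since even with no member marked the unadjusted p of Fisher's exact test is above 0.05. Each of the 17 had a higher share than all genes in both replicates. Some genes are members of several lists, so the calls are not independent of each other. Neighbouring genes share domains, genes are not independent replicates, and these p-values compare groups of genes, not samples. With genes within 100 kb of each other counted once, the same 17 calls were made.

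Across 26 gene families taken by symbol, 16 were marked more often than other genes and 5 less often. Every member was marked among Lhx (8 of 8), Pax (9 of 9), Irx (6 of 6) and Dlx (6 of 6) genes, which encode homeodomain or paired-domain factors, along with 13 of 14 Nkx genes, 10 of 13 Tbx genes and 24 of 46 Fox genes. Hox genes (39 of 39) and Wnt genes (18 of 19) were counted above, and Sox (8 of 19), sine oculis homeobox (4 of 6), Fgf (13 of 22), Bmp (7 of 12) and solute carrier genes (Slc, 69 of 371) also passed. Potassium channel genes (Kcn) were marked in 43 of 94 (45.7%, adjusted p = 2.60e-14) and calcium channel genes (Cacn) in 11 of 26 (42.3%, adjusted p = 3.03e-04), by Fisher's exact test. The 5 families below the rest were olfactory receptors (Olfr, 4 of 1135, adjusted p = 3.39e-61), vomeronasal receptors (Vmn, 0 of 331, adjusted p = 2.36e-19), zinc finger proteins (Zfp, 17 of 394, adjusted p = 3.56e-08), genes with ribosomal protein symbols (Rp, 1 of 98, adjusted p = 8.47e-05) and clustered protocadherins (Pcdh, 0 of 57, adjusted p = 8.28e-04), each by Fisher's exact test. Keratin (Krt, 5 of 53), cytochrome P450 (Cyp, 11 of 100), interleukin and interleukin receptor (Il, 16 of 82), respiratory complex I (Nduf, 1 of 33) and proteasome genes (Psm, 3 of 40) did not pass. Because families were taken by symbol, the Il family mixes ligand and receptor genes, and the Rp family also holds ribosomal S6 kinase genes. Without replicate 1, Il genes (17 of 82, adjusted p = 0.0325) and Nduf genes (0 of 33, adjusted p = 0.0336) did, by Fisher's exact test. They also did among CpG-rich promoters (6 of 10, adjusted p = 0.00211, in a range up to 1.00 over the alternatives, and 0 of 26, adjusted p = 0.0329, in a range up to 0.466, Fisher's exact test). How reads that match several near-identical genes were treated, which bears on receptor families above all, is not given in the sources used here. The protocadherin call was lost with peaks of −log10 q of 5 or more (0 of 57, adjusted p = 0.154), among CpG-rich promoters (0 of 22, adjusted p = 0.0769) and with clustered genes counted once, which left 2 (adjusted p = 1.00, in a range from 3.12e-04, Fisher's exact test). Among CpG-rich promoters no olfactory receptor and 1 vomeronasal receptor gene were left, so neither call could be made there. With clustered genes counted once the sine oculis call was lost too (2 of 3, adjusted p = 0.0588, in a range from 4.70e-04, Fisher's exact test). With peaks touched by both replicates alone, a check chosen after seeing the data, the calls of calcium channel genes (adjusted p = 0.0524) and solute carriers (adjusted p = 0.215) were lost by Fisher's exact test, and the latter also among CpG-rich promoters (33 of 168, adjusted p = 0.109, Fisher's exact test). Replicate 1 alone marked 105 Slc, 12 Olfr, 3 Vmn, 2 Rp and 9 Krt genes, and replicate 2 alone 61, 7, 0, 1 and 3, with the same calls. Each replicate alone marked 2 of 57 Pcdh genes, none of them in both, again with the same call. Over all alternatives the adjusted p of Fisher's exact test ran from 4.55e-07 to 0.449 for calcium channel genes and from 1.05e-06 to 0.284 for solute carriers, the highest values with peaks of −log10 q of 5 or more.

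The mark varied with the CpG content of the promoter. Genes were classed by the ratio of observed to expected CpG in the 1 kb around the 5′ end, and the mark was counted at any TSS. Of 8065 CpG-poor genes (ratio under 0.35) 442 were marked (5.48%, Wilson interval 5.005% to 5.999%). Of 3790 middle ones 876 were (23.1%, 21.8% to 24.5%), and of 10083 CpG-rich ones (ratio over 0.6) 1501 were (14.9%, 14.2% to 15.6%). With the mark counted at the 5′ end only, the shares were 3.21%, 20.0% and 13.2%. CpG-rich genes were marked at any TSS 2.72-fold as often as CpG-poor ones (Fisher's exact test, two-sided, p = 5.80e-98), 1.95-fold in replicate 1 and 2.33-fold in replicate 2. Replicate 1 alone marked 9.85% of CpG-poor genes and replicate 2 alone 5.91%. The middle class had the highest share in both replicates, 30.7% in replicate 1 and 21.3% in replicate 2.

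Chromosome X differed between the replicates. Peaks covered 2.57 kb per Mb of X in replicate 1, 0.311 times the median autosome, and 4.49 kb per Mb in replicate 2, 1.05 times the median autosome. Replicate 2 had 2890 peaks on X against 1651 in replicate 1, or 175 per 100, whereas on the 19 autosomes it had 40.1 to 55.6 per 100. In the replicated set X carried 1.92 kb per Mb, below the lowest autosome (chromosome 3, 2.91 kb per Mb), while chromosome 19 carried the most (11.5 kb per Mb). Promoter peaks were found at 5.91% of X genes in that set, against a median of 13.3% over autosomes. In replicate 1 alone these shares were 7.17% and 18.3%, but in replicate 2 alone they were close, at 11.8% and 11.9%. No list has a peak on Y. With 1 pool per replicate no test between the chromosomes was made.

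**Figure D4:**
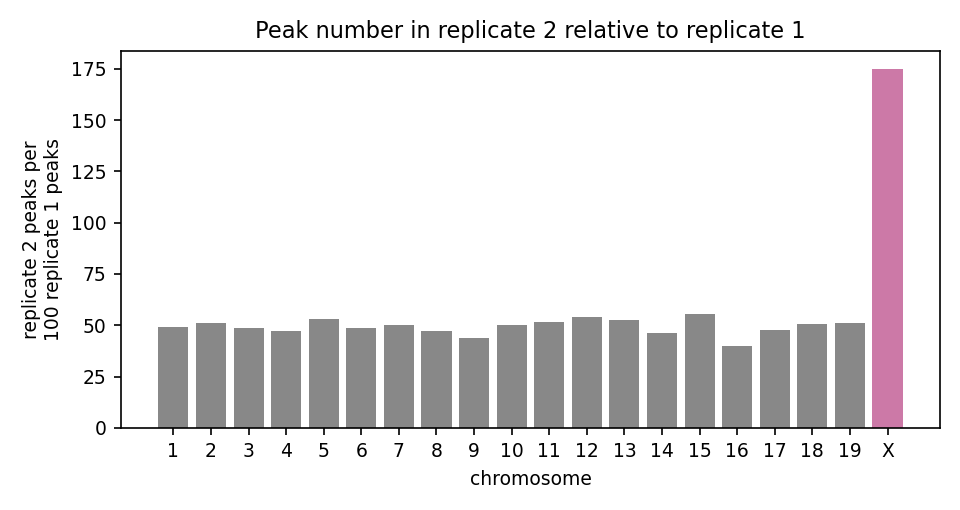
Number of replicate 2 peaks per 100 replicate 1 peaks (y axis) on each chromosome (x axis), with X in pink. The autosomes lie between 40.1 and 55.6, and X lies at 175.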

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

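The peaks touched by both replicates and the autosomes-only comparison were chosen after seeing the data; all other alternatives were planned. Of the 17 lists marked more often than other genes, 13 kept direction and side of the threshold under all 13 alternatives, with Hox cluster genes 82.4 to 92.6 points above other genes. Forebrain factors lay below midbrain, hindbrain and spinal cord factors under every alternative run, by −65.9 to −30.2 points. The cause of the changes below was not tested unless stated. Peak lists carry no read depth, so how far depth limits the weaker list, replicate 2, cannot be given.

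Differences from other genes, in percentage points, changed as follows. With peaks of −log10 q of 5 or more, which leaves 4821 peaks, the threshold was missed by cortical excitatory neuron factors (4.49), endothelial and mural markers (11.6), glutamate, GABA and ion channel genes (8.76) and the cortical against ventral comparison (−26.8), and without passing it the sign turned for pan-neuronal genes (−0.0415), astrocyte markers (−5.04), erythroid markers (2.65) and Il genes (−0.164). With peaks of signal at or above the median, cortical factors missed the threshold (14.6) and astrocyte markers turned (−9.18). With 2.5 kb windows, endothelial markers (17.4) and forebrain against other germ layers (−12.3) missed it. With the 5′ end only, cell cycle inhibitors (14.3) and cortical against ventral factors (−30.1) did. Among CpG-rich promoters, which leaves fewer genes, cortical factors missed it (15.9), neural progenitor genes (−5.80) and Cyp genes (7.34) turned, and 3 families lay below the rest instead of 5 (zinc finger, Rp and Nduf genes). Cyp genes also turned with clustered genes counted once (8.57), and erythroid markers gave no value, having no CpG-rich member. With the pooled set housekeeping genes passed it (−14.6). With 1 replicate left out, the range was 23.9 to 29.5 for cell cycle inhibitors, 8.87 to 24.4 for neural progenitor genes and 1.02 to 6.56 for microglia markers, which turned without passing the threshold.

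With 1 replicate left out, marked genes ranged from 12.2% to 17.7%, promoter bases from 17.0% to 19.3%, domains from 11630 to 22482, domains over 10 kb from 485 to 900, and X density from 0.311 to 1.05 times the autosomal median. Hox coverage ranged from 74.4% to 86.8% (HoxA), 61.5% to 76.1% (HoxB), 76.3% to 89.3% (HoxC) and 67.8% to 84.8% (HoxD). With −log10 q of 5 or more, 5.04% of genes were marked, HoxA coverage was 79.6%, and 2083 domains formed, 162 of them over 10 kb. Peaks of signal at or above the median gave 4612 and 339, and peaks touched by both replicates gave 5153 domains, fewer peaks being joined in each case. Joins over 1 kb and 10 kb gave 291 and 940 domains over 10 kb.

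Overlap of replicate 1 and replicate 2 peaks was 43.6% and 53.1% with equal peak numbers (Jaccard 32.2%, kappa 0.736), 13.2% and 90.4% with −log10 q of 5 or more (Jaccard 13.7%, kappa 0.272, 243 genes in both), where replicate 1 kept 8038 peaks and replicate 2 kept 1129, and 20.5% and 55.0% with 50% of the peak covered. On autosomes alone 68.1% of replicate 2 peaks were overlapped (Jaccard 27.9%). Kappa was 0.632 with 2.5 kb windows.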

Other observations

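The patterns and tests in this part, and the genes and regions named, were chosen after the main results were seen, and they rest on the same peaks. Long intergenic non-coding RNA genes more than 5 kb from any protein-coding start site had a replicated peak within 1 kb of their own start in 176 of 5143 cases (3.42%, Wilson interval 2.96% to 3.95%), 1.47-fold the mean of 20 random placements, none of which gave more than 140. The share depended on the replicate, with 6.53% in replicate 1 and 3.27% in replicate 2. Antisense genes (46 of 1366, 1.21-fold) and microRNA genes (39 of 1484, 1.02-fold) lay below the highest of those placements, with 6.73% and 3.66% for antisense and 4.58% and 2.02% for microRNA genes in replicates 1 and 2. Among the non-coding genes with the most peak bases in the 10 kb around the start were Mir196a-1 in HoxB (chromosome 11, 96265164 to 96265265, replicate mean 8678 ± 795 bp, SD, n = 2), Hotair in HoxC (chromosome 15, 102944062 to 102947730, 7801 ± 1377 bp) and Tlx1os (chromosome 19, 45154057 to 45159304, 6956 ± 1311 bp).

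Of all 7805 domains, 5863 (75.1%) held no start site of a protein-coding gene. Among the 1368 domains over 5 kb 546 (39.9%) held none, and among the 534 over 10 kb 200 (37.5%) held none. The longest of these, 55.3 kb at chromosome 7 from 143329929 to 143385228, overlapped Kcnq1, which lies in an imprinted gene cluster, and the nearest protein-coding start site was that of Cdkn1c at 74.1 kb. The replicates covered 42.9% ± 13.8 (SD, n = 2) of it. The next, 54.2 kb at chromosome 1 from 89663168 to 89717340, overlapped Agap1 and was covered to 37.8% ± 18.99. A pair followed within the annotated span of Fgfr2 on chromosome 7, 46.9 kb from 131705608 to 131752471 and 46.3 kb from 131764898 to 131811147. The nearest protein-coding start sites to this pair were not those of Fgfr2 but of Bub3 at 144.9 kb and of Gpr26 at 155.3 kb, in the same order. One of 41.6 kb on chromosome 13 from 72273888 to 72315492 overlapped no gene, and its nearest protein-coding start site was that of Irx1 at 310.2 kb.

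Replicate 2 had more peaks on X than replicate 1 and fewer on each autosome, as the plot of peak number by chromosome shows. A few crowded regions alone do not account for the ratio. Without the 8 bins of 1 Mb with the largest excess, X still had 180 replicate 2 peaks per 100 replicate 1 peaks (95% interval 165 to 195). Those bins held many of the X peaks: 877 of 1651 in replicate 1 and 1576 of 2890 in replicate 2 were left. Of 84 bins of X with peaks, 64 had more peaks in replicate 2 and 10 had fewer. For X peaks shared by the replicates, a shift by 10 percentile points or more is argued against. They sat at the 35.7th percentile of shared autosomal peaks by signal in replicate 1 and at the 35.9th in replicate 2. The difference was 0.194 points (bootstrap interval −3.65 to 7.95). Only 17.2% of replicate 2 peaks on X were shared, against 68.1% on autosomes, so the test left out most X peaks of replicate 2. An effect of control files or the sex balance of the pools on those peaks stays open, as does a smaller shift. Weak peaks near the calling threshold are a candidate explanation: among peaks with q of 0.05 or less X had 28.5 per 100 (25.3 to 32.1), within the 20.0 to 31.9 of the autosomes, and only 11.9% of replicate 2 peaks on X reached that q, against 38.9% on autosomes. Why weak peaks gathered on X was not tested.

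Forebrain factor promoters that carried the mark held less of it: a median of 3747 bp of replicated peaks in the 10 kb window for 37 genes, against 7473 bp for 42 midbrain, hindbrain and spinal cord factors (permutation p = 1e-05, the smallest that 100000 draws can give), with 4086 against 7101 bp in replicate 1 and 1644 against 5215.5 bp in replicate 2. By list the forebrain medians were 2618 bp (telencephalic patterning), 3534 bp (cortical) and 5226 bp (ventral). Marked blood factors (4800.5 bp) and epidermis genes (4197 bp) also lay below 7473 bp, with mesoderm (7208.5 bp) and endoderm factors (7261 bp) nearer to it. The gap between the forebrain and the other neural factors remained among promoters with a CpG ratio above 0.6, where the difference was −4685 bp (26 and 31 genes, permutation p = 1e-05). The groups were not matched on the ratio within that class. The ratio was also taken at the 5′ end and not over the 10 kb window, so a part of CpG content in the gap stays open. Genes that share a domain are too few to account for the gap, since 1 gene per domain left 36 and 42 genes and a difference of −3484 bp. A mark in only part of the forebrain cells, as a hypothesis, and a weaker mark in every cell both stay open. The highest signal in the window was also lower (5.21 against 6.95, a difference of −1.74), but it is taken over the same peaks and rises with their bases, so it does not decide.

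Promoters of middle CpG ratio carried the mark more often than CpG-rich ones. By deciles of genes ordered by the ratio, the share rose from 2.01% to 24.4% in the 5th and 24.1% in the 6th and fell to 9.21% in the 10th. The number of annotated start sites runs the other way, with a median of 3 per gene in the middle class and 4 in the CpG-rich class, and with the 5′ end alone the classes stood at 20.0% (18.8% to 21.3%) and 13.2%. Families below the rest hold too few CpG-rich genes to account for it, since 9781 of 10083 lie outside them and leaving them out could barely move that class (15.2%, against 23.97% in the middle class), while other families without the mark were not examined. No biological explanation was tested.

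In all 4 lists 2 of the 100 peaks with the lowest p-values had a signal in the lowest quartile of the list; they lie at chromosome 17 from 39843073 to 39848886 in the replicated set, where RefSeq has the ribosomal RNA pseudogene Rn18s-rs5 (39846354 to 39848202) and part of the non-coding gene AY036118 (39848112 to 39898385), and reach a −log10 p of 46.5 against 61.6 for the highest peak of that set.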
